A study of Saccharomyces cerevisiae with 28 samples.

How the data were processed

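Total RNA was extracted with acid phenol and copied into cDNA with aminoallyl-dUTP, per the labels' protocols, and mutant and wild-type samples were labelled with Cy5 or Cy3 and hybridised together. Channel 1 held the mutant on all 28 arrays, in Cy5 on the first array of each of the 14 pairs and in Cy3 on the second, per the labels. The deposited value table gives 1 log ratio per spot, read as log2, and the authors' scanner, background correction, normalization, scale, log base and direction are not given in the sources used here. The values were treated as mutant over wild type without turning any array, because channel 1 is the mutant. In addition, 12 of 14 pairs correlated above 0 once the mean of each dye orientation was removed, so both arrays run the same way in those pairs. By this correlation csn9 (r = -0.05) and tgs1 at 30 °C (r = -0.37) go against it. In tgs1 at 30 °C the mating type genes nevertheless had one sign on both arrays, MF(ALPHA)1 at -4.62 and -4.45 and MFA2 at 1.89 and 2.54. The check does not tell mutant over wild type from its inverse. Strain background, mating type, and whether strains shared a wild-type RNA are not given in the sources used here.

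Every table column was mapped to a sample by its name, with 0 columns left unmapped. Probe names came from the platform annotation supplied with the data, updated through its gene identifiers to the RefSeq gene table of assembly R64, and 982 of 982 identifiers matched. Of 1536 probes, each printed 6 times, 1457 had 1 gene symbol, none had several and 79 had none; the last stay out of all gene results. Genes had 1 probe (747), 2 (4), 3 (222) or 4 (9), and 916 were protein coding, 64 tRNA genes and 2 pseudogenes. Because the platform layout names no genome build, no coordinates are printed.

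Each array was centred on its median, the 6 spots of a probe were averaged, the 2 arrays of a pair were averaged so that the dye effect cancels, and the probes of a gene were averaged. Probes of one gene can disagree, as the class contrast shows, and what each probe follows is not given in the sources used here. A probe needed a value on at least 1 array of every pair; 1 probe was left out and 1 value rests on 1 array. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) to 14 pair means in 10 strain-by-temperature groups, 8 of 1 pair and 2 of 3 pairs, with 4 residual and 6.33 prior degrees of freedom and a prior SD of 0.065. The groups of 1 pair are assumed to vary like the time points at 16 °C. Tests were 2-sided with Benjamini-Hochberg adjustment at 0.05 over all genes of a comparison. The fit over 28 arrays with a dye term, in which the dye term is the same as a block for the array number, had 13 residual degrees of freedom and a prior SD of 0.194. The array numbers mark dye orientations, not cultures.

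Each comparison set a strain's log ratio against 0, its matched wild type being in the other channel. Variation of the wild type thus enters the ratios and is not estimated apart from that of the mutant. Further comparisons set 16 °C against 30 °C within tgs1 and ynr004w, and tgs1 against ynr004w at 16 °C. Named genes followed a rule fixed before the data were examined: the deleted gene and its neighbours; among genes past the threshold with one sign on every array of the comparison, the 10 highest and 10 lowest (the 5 highest and 5 lowest as values where none passed, and for the comparisons of temperatures and of both strains, where one sign means that the arrays of both groups did not overlap); and up to 4 members of each list whose shift passed. Gene lists were fixed at the same time and tested with camera at a preset correlation of 0.01 and with an estimated one, adjusted over 140 tests together. Lists with fewer than 3 measured genes were not tested. Counts adjusted over the list alone reuse the p-values of the fit over pair means, so they do not check its error. The intron list was taken from general knowledge, because no intron annotation was given.

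Intron retention was planned only if probe classes could be read from a source; none gives them, so it was left out. The contrast of class A with classes B and C was added after the data were seen and used the same limma fit on the per-gene difference; 188 genes had linked wells and 187 were tested. Wells were linked when 2 probes of a gene lay 2 blocks apart in the same row, in the same column or 6 columns on.

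The scripts were tested on simulated data in which 200 of 982 genes changed by 0.5 or 1 log2 units. With all pairs drawn at the fitted spread, 100% and 100% of the changed genes were recovered in csn12, with 11 of 782 unchanged genes called; in tgs1 at 16 °C 100% and 100%, with 5 called. With single pairs drawn at the spread between arrays, 98% and 100% were recovered in csn12 but 172 of 782 unchanged genes were called, against 100%, 100% and 7 in tgs1 at 16 °C. The fit with a dye term recovered 61% and 99% in csn12, with 3 called, and 96% and 100% in tgs1 at 16 °C, with 13 called.

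Alternatives fixed before the data were examined were ratios as deposited, arrays scaled to one spread, the dye-term fit, leaving out either array of the pairs, 8 strain groups, leaving out single time points, medians over probes, probes with a value on all arrays, robust eBayes, and stricter thresholds. Leaving out class A probes, centring on genes with 1 probe, using class B or C alone as the reference, a term for the time point in the comparison of tgs1 with ynr004w, and gene lists drawn from the array were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.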

Results

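Relative transcript levels were measured in 8 deletion strains of budding yeast on spotted, splicing-specific microarrays, each mutant hybridised together with wild-type cells collected under the same conditions. The mutants lacked CSN12 (YJR084W), THP3 (YPR045C, named YPR045C in the labels), IST3 (YIR005W), CSN9 (YDR179C), PCI8 (YIL071C), ISY1 (YJR050W), TGS1 (YPL157W) or SWM2 (YNR004W, named ynr004w in the labels). These are non-essential genes that large-scale genetic or protein interaction screens had tied to splicing, and the question was how their loss changes it. The csn12, YPR045C, ist3, csn9, pci8 and isy1 strains were sampled in logarithmic growth at 30 °C. The tgs1 and ynr004w strains were sampled at 30 °C (0 min) and at 10, 25 and 40 min after a shift to 16 °C. Each of the 14 conditions had 2 arrays with the dyes exchanged, 28 arrays in all, averaged to 1 pair mean per condition. Between 8893 and 9199 of the 9216 spots had a value on an array, and array medians lay between -0.0282 and 0.0279. The spots carried 1536 probes in 6 copies, and 982 genes were named by at least 1 probe. The number of arrays limits the precision.

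Values below are mean log2 ratios ± SE, taken as mutant over wild type with base 2. Neither the direction nor the log base is stated in the sources used here, so both are likely rather than settled. The basis for the direction is that the mutant is channel 1 on every array and that the arrays of most pairs run the same way once the effect of dye is removed. The 2 arrays of a pair correlated above 0 in only 4 of 14 pairs as deposited, and the mean profiles of both dye orientations correlated at r = -0.5. After each orientation's mean was taken off, 12 of 14 pairs correlated above 0, the exceptions being csn9 (r = -0.05) and tgs1 at 30 °C (r = -0.37). YPR045C and ynr004w, each against its own wild type, correlated at r = -0.54 over all genes, but at 0.32 without the mating type and deleted genes and at a Spearman 0.38 over all genes, so this value rests on few genes and does not settle the direction either way. If the ratios ran the other way, every "higher" and "lower" would be exchanged.

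The deleted genes did not check the labels. IST3 stood at 0.15 in the arrays labelled ist3 (0.63 and -0.32 on the single arrays), within the -0.24 to 0.27 of the other 13 pairs. ISY1 stood at -0.12 in the arrays labelled isy1 (adjusted p = 0.116), slightly below the lowest of the other 13 pairs, -0.11. TGS1 stood at -0.09 in the arrays labelled tgs1 at 30 °C (adjusted p = 0.378). At 16 °C it was at -0.28 (adjusted p = 0.000331), but single arrays ran from -1.16 to 0.51, the fit over single arrays gave adjusted p = 0.0925, and the 10 pairs of other strains reached -0.31. None of the 3 genes therefore showed the loss a deletion would give, and whether their single probes lie inside the deleted parts is not known. CSN12, THP3, CSN9, PCI8 and SWM2 had no named probe. Strains are called by their labels below on these terms. Among genes next to a deleted gene, RPL43A beside THP3 was at 0.33 ± 0.08 in YPR045C (adjusted p = 0.0235, but 0.91 over single arrays). RPC34 beside SWM2 was at 0.02 in ynr004w at 30 °C (adjusted p = 0.889) and at -0.08 at 16 °C (adjusted p = 0.0792).

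The number of genes apart from wild type was 554 of 982 in ist3, 453 in tgs1 at 16 °C, 414 in isy1, 361 in csn12, 322 in ynr004w at 16 °C, 314 in pci8, 215 in csn9, 186 in YPR045C, 58 in ynr004w at 30 °C and 56 in tgs1 at 30 °C. These counts used limma on the pair means at adjusted p under 0.05, in which the 8 conditions with 1 pair are assumed to vary like the 16 °C time points. Each 16 °C group averaged 3 pairs, with a median SE of 0.037 against 0.065 in the groups of 1 pair. Counts at 16 °C and 30 °C therefore differ in power and do not measure an effect of cold. When the 28 arrays entered singly with a dye term, so that the spread came from the 2 arrays of each pair, the counts were 76, 98, 95, 46, 61, 10, 3, 10, 9 and 9 in the same order. In simulated data with single pairs drawn at the spread between arrays, 172 of 782 unchanged genes were called in csn12. Many calls of the log-phase strains may therefore rest on too small an error. The drawn spread also holds any dye bias that differs between pairs and cancels in a pair mean, so 172 is not an estimate for the real fit. In the fit over pair means the p-values rest on the spread among the 16 °C time points of tgs1 and ynr004w. That spread also holds any change over time. Over single arrays the p-values measure only the spread between these hybridisations. It may be technical, since nothing says that the 2 arrays of a pair hold separate cultures. The highest and lowest genes named had one sign on every array of their condition; genes named as members of a list need not.

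**Figure D1:**
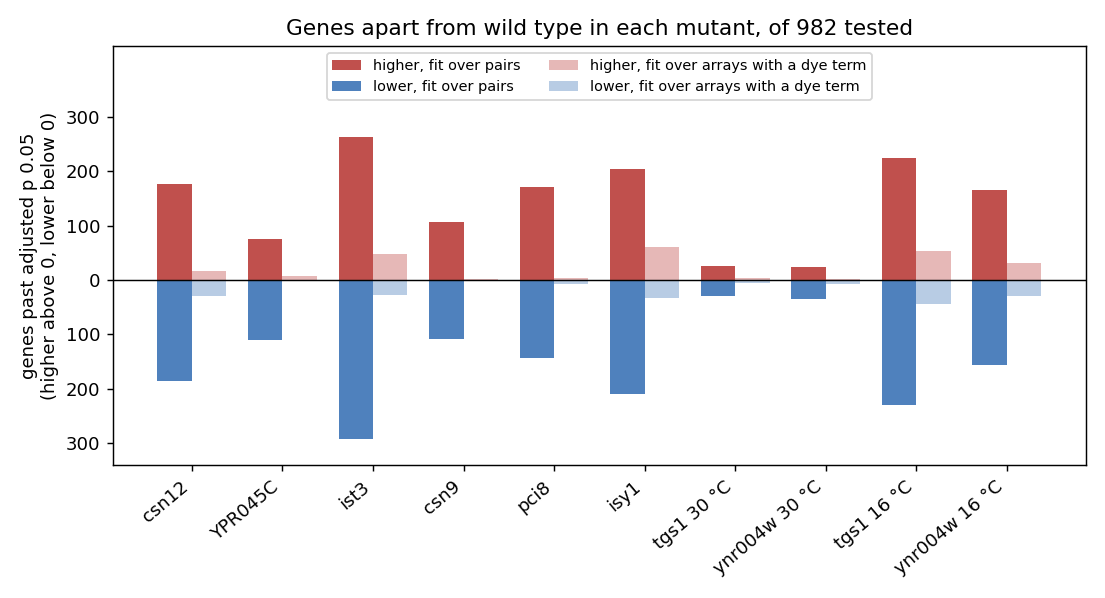
Genes past adjusted p 0.05 in each mutant against its wild type, out of 982 tested; bars above 0 count higher genes and bars below 0 lower genes, dark for the fit over pair means and pale for the fit over single arrays with a dye term. The ist3 bars reach 262 higher and 292 lower, and the pale bars are shorter in every strain.

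In csn12, heat shock and chaperone genes rose. HSC82, which encodes an Hsp90, was at 1.28 ± 0.12 (adjusted p = 3.97e-05), HSP104, the protein disaggregase, at 1.21 ± 0.13, and KAR2, the Hsp70 of the endoplasmic reticulum, at 1.20 ± 0.10. Of 7 measured members of the chaperone list 6 rose and 1 fell, the same adjusted over the list alone; SIS1 was at 0.85, SSA1 at 0.63 and SSA4 at 0.58. The list shifted up (camera, adjusted p = 0.00486; adjusted p = 0.668 with an estimated correlation). YAP6, a bZIP transcription factor, was the highest gene at 1.33 ± 0.10, followed further down by GCN3, a subunit of eIF2B, at 1.13 and MATALPHA1 at 1.06. The tRNA genes YNCB0018W (-1.62 ± 0.11) and YNCD0021C (-1.29 ± 0.06) were lowest, and MFA1, an a-factor gene, was at -1.13, CGR1, which acts in rRNA processing, at -1.08, SUP11, a tRNA gene, at -1.04 and RGS2 at -0.93. Of 29 ribosome biogenesis genes 10 fell and 2 rose, the same adjusted over the list alone, among them RRP5 (-0.71) and NOP10 (-0.70); the list's shift down (adjusted p = 0.0428; adjusted p = 0.762 with an estimated correlation) was lost in the fit over single arrays (adjusted p = 0.0563), with medians over probes (0.0545), with centring on genes of 1 probe (0.0524) and without the class A probes described below (0.0573). Over single arrays 4 chaperone genes passed higher and 0 lower, and 0 ribosome biogenesis genes higher and 2 lower. In all, 176 genes were higher and 185 lower, against 16 and 30 over single arrays. Centring on genes with 1 probe moved the split to 141 higher and 219 lower.

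In YPR045C, genes specific to alpha cells were far above wild type and those specific to a cells far below. MF(ALPHA)1, the main alpha-factor gene, was at 4.84 ± 0.20 (28.7-fold, adjusted p = 4.99e-08), MATALPHA1 at 3.99 ± 0.12, MF(ALPHA)2 at 3.02 ± 0.18 and STE3, the a-factor receptor, at 2.71 ± 0.15. The a-factor genes MFA2 and MFA1 were at -3.16 ± 0.10 and -2.14 ± 0.17. All 3 alpha-specific genes rose, also adjusted over the list alone (list adjusted p = 1.37e-06; adjusted p = 0.599 with an estimated correlation). The 4 measured pheromone response genes rose too, also adjusted over the list alone: KAR4 was at 0.88, SST2 at 0.82, FUS3 at 0.66 and STE12 at 0.62 (list adjusted p = 1.11e-05; adjusted p = 0.599 with an estimated correlation). HMRA2, named as a gene of the silent mating type locus, was at 0.98, close to MATALPHA2 at 0.93. Whether the probes tell these genes apart is not given in the sources used here. Outside these groups tC(GCA)Q, a mitochondrial tRNA gene, was at -0.80 and TOA2, a subunit of TFIIA, at -0.54. Over single arrays all 3 alpha-specific genes passed, but only 2 of the 4 pheromone response genes. There were 76 genes higher and 110 lower, against 8 and 2 over single arrays.

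In ist3, whose product belongs to the RES complex of the spliceosome, the same mating type genes moved: MF(ALPHA)1 was at 5.24 ± 0.20 (37.8-fold, adjusted p = 3.35e-08), MATALPHA1 at 3.25, STE3 at 2.23 and MF(ALPHA)2 at 1.90, while MFA2 was at -2.10 and MFA1 at -1.47. The alpha-specific list rose with 3 of 3 genes (adjusted p = 0.00244; adjusted p = 0.647 with an estimated correlation), and the pheromone response list with 4 of 4, SST2 at 0.81 and STE12 at 0.61 (adjusted p = 0.00698; adjusted p = 0.599 with an estimated correlation), with the same counts adjusted over the list alone. Of 29 ribosome biogenesis genes 18 rose and 3 fell, the same adjusted over the list alone; NOP56 was at 0.71, SPB1 at 0.51 and RRP5 at -0.47 (adjusted p = 0.00601; adjusted p = 0.668 with an estimated correlation). GTS1 (0.86) and RRP6, the nuclear exosome nuclease (0.69), were among the highest others, and RPS22B (-0.92), GPD1, which makes glycerol 3-phosphate (-0.82), SPL2 (-0.75) and PPZ1 (-0.64) among the lowest. Of 125 ribosomal protein genes 44 rose and 15 fell, the same adjusted over the list alone, with RPS9A at 0.71 (adjusted p = 0.00508; adjusted p = 0.762 with an estimated correlation). That shift ended and turned down without the class A probes (adjusted p = 0.68) and with medians over probes (0.932). Over single arrays 2 ribosome biogenesis genes passed higher and 0 lower, and 16 ribosomal protein genes higher and 1 lower. All 3 alpha-specific genes and 3 of the 4 pheromone response genes passed there. There were 262 genes higher and 292 lower, against 48 and 28 over single arrays.

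The csn9 and pci8 strains each lack a protein of the COP9 signalosome or a related complex. In csn9, PSH1, a ubiquitin ligase gene, was at 0.79 ± 0.06 (adjusted p = 3.55e-05), the highest gene with one sign on both arrays, with GCN1, an activator of the Gcn2 kinase, at 0.63, SSA2, an Hsp70, at 0.60 and DED1, an RNA helicase, at 0.53. The lowest were TRR4 (-0.96), YNCD0021C (-0.93), YNCB0018W (-0.87) and SUP16 (-0.86), all tRNA genes, and ITT1 at -0.91. The mitochondrial tRNA gene tA(UGC)Q was higher than PSH1 at 1.20 ± 0.09 (adjusted p = 1.26e-05), but its arrays had opposite signs and it did not pass over single arrays (adjusted p = 0.228). In pci8, SIN3, of the Rpd3 histone deacetylase complexes, was at 0.67 ± 0.08 (adjusted p = 0.000395), GCN1 at 0.65 and HTA1, encoding histone H2A, at 0.60, while YNCB0018W was at -1.51, YNCD0021C at -1.30 and HAC1, the transcription factor of the unfolded protein response, at -0.59. Ribosomal protein genes shifted up in both: in csn9 27 rose and 9 fell, or 31 and 10 adjusted over the list alone, with RPP0 at 0.53 but RPS31 at -0.65 (adjusted p = 0.00434; adjusted p = 0.762 with an estimated correlation). In pci8 45 rose and 11 fell, or 46 and 11 adjusted over the list alone, with RPL37A at 0.52 and RPL11A at 0.50 but RPS31 at -0.62 (adjusted p = 0.000648; adjusted p = 0.762 with an estimated correlation). Over single arrays 0 ribosomal protein genes passed in csn9, and in pci8 2 passed higher and 0 lower. Counts over all genes were 106 higher and 109 lower in csn9, against 1 and 2 over single arrays. They were 171 and 143 in pci8, against 3 and 7. Centring on genes with 1 probe moved the csn9 split to 139 higher and 88 lower, and scaling the arrays to one spread raised the totals to 468 in csn9 and 536 in pci8.

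In isy1, which lacks a member of the Prp19-associated complex of the spliceosome, GTS1 was at 2.41 ± 0.15 (adjusted p = 1.28e-06) and TDH1, a glyceraldehyde-3-phosphate dehydrogenase gene, at 2.33 ± 0.08 (adjusted p = 1.26e-08). The tRNA genes YNCD0021C (2.03), YNCB0018W (1.47) and SUP16 (1.35) were also high, as was TYE7, an activator of glycolytic genes, at 1.23. CBC2, the small subunit of the nuclear cap-binding complex, was lowest at -1.99 ± 0.08 (adjusted p = 4.44e-08), followed by RPS14B (-1.25), RPS22B (-1.20), HTA1 (-1.19) and RPL7B (-1.12). Of 125 ribosomal protein genes 55 fell and 9 rose, or 56 and 11 adjusted over the list alone (adjusted p = 1.2e-05; adjusted p = 0.741 with an estimated correlation). Of 7 chaperone genes 4 rose and none fell, the same adjusted over the list alone, with SSA1 at 1.01 and SSE2 at 0.49 (adjusted p = 0.0182; adjusted p = 0.741 with an estimated correlation). Over single arrays 21 ribosomal protein genes passed lower and 2 higher, and 2 chaperone genes higher and 0 lower. There were 204 genes higher and 210 lower, against 61 and 34 over single arrays. Centring on genes with 1 probe moved the split to 158 higher and 277 lower.

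TGS1 encodes the enzyme that trimethylates the cap of small nuclear and nucleolar RNAs. At 30 °C the tgs1 and ynr004w strains showed mating type genes moving against the direction seen in ist3. In tgs1, MFA2 was at 2.21 ± 0.10 (adjusted p = 2.81e-07) and MFA1 at 1.23, while MF(ALPHA)1 was at -4.53 ± 0.20, STE3 at -1.86 and MATALPHA1 at -0.95. In ynr004w, MFA2 was at 2.02 ± 0.10 (adjusted p = 4.77e-07) and MFA1 at 1.36, while MF(ALPHA)1 was at -4.44 ± 0.20, STE3 at -2.46 and MATALPHA1 at -1.16. The alpha-specific list fell with 3 of 3 genes in tgs1 (adjusted p = 1.37e-06) and in ynr004w (adjusted p = 2.7e-07), also adjusted over the list alone (adjusted p = 0.599 with an estimated correlation in each). TDH1 was at -1.35 and -1.72 in tgs1 and ynr004w, and RPS22B at -0.70 and -0.81. CUP1-2, a metallothionein gene, was at 0.51 in tgs1, and HSC82 at 0.58 in ynr004w. Totals were 26 higher and 30 lower in tgs1, against 3 and 6 over single arrays, and 23 and 35 in ynr004w, against 2 and 7; scaling the arrays left 3 higher and 15 lower in tgs1. Leaving out the 25 min point of tgs1 or the 40 min point of ynr004w at 16 °C, from which the spread is taken, left 35 or 28 genes in tgs1, and the latter 27 in ynr004w. With both temperatures of a strain in one group, 414 genes passed in tgs1 and 294 in ynr004w.

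Ribosome biogenesis genes shifted up in both strains at 30 °C. In tgs1 5 of 29 rose and none fell, or 16 and none adjusted over the list alone, with HAS1, an RNA helicase, at 0.41, SPB1 at 0.37 and RLP7 at 0.36 (adjusted p = 3.6e-06; adjusted p = 0.599 with an estimated correlation). In ynr004w 6 rose and none fell, or 7 and none adjusted over the list alone, with NOP58 at 0.29 and SPB1 at 0.28 (adjusted p = 3.22e-05; adjusted p = 0.611 with an estimated correlation). Of 29 RNA decay genes 2 rose and none fell in tgs1, the same adjusted over the list alone: XRN1, the cytoplasmic exonuclease, and RRP46, of the exosome, were both at 0.25 (adjusted p = 0.00643; adjusted p = 0.599 with an estimated correlation). Of 80 intron-containing genes outside the ribosomal protein group 3 fell and none rose in tgs1, the same adjusted over the list alone, ERV41 at -0.38 and COX5B at -0.26 (adjusted p = 0.00434; adjusted p = 0.668 with an estimated correlation). In ynr004w 4 fell and none rose, or 3 adjusted over the list alone, COX5B at -0.42 and VMA10 at -0.33 (adjusted p = 0.00421; adjusted p = 0.668 with an estimated correlation). The ribosomal protein list was called up with 4 genes higher and 5 lower in tgs1, or 7 and 5 adjusted over the list alone (adjusted p = 0.00954; adjusted p = 0.762 with an estimated correlation), and with 4 and 4 in ynr004w, the same adjusted over the list alone (adjusted p = 0.0139; adjusted p = 0.762 with an estimated correlation). Without the class A probes both calls ended and turned down (adjusted p = 0.414 and 0.656), as they did with medians over probes (0.887 and 0.982).

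At 16 °C, over 3 time points each, MFA2 was at 2.62 ± 0.06 in tgs1 (adjusted p = 3.68e-10) and 2.58 ± 0.06 in ynr004w, and MF(ALPHA)1 at -4.24 ± 0.11 and -4.62 ± 0.11. The alpha-specific list fell in tgs1 (3 of 3, also adjusted over the list alone; adjusted p = 0.000136; adjusted p = 0.611 with an estimated correlation) and in ynr004w (3 of 3, also adjusted over the list alone; adjusted p = 5.8e-06; adjusted p = 0.599 with an estimated correlation). All 4 pheromone response genes fell in ynr004w, also adjusted over the list alone, SST2 at -0.38 and KAR4 at -0.34 (adjusted p = 0.00698; adjusted p = 0.599 with an estimated correlation). TDH1 was at -1.48 in tgs1 and -1.57 in ynr004w, RPS22B at -0.74 and -0.84, and GTS1 at 0.96 and 0.45. RPP0, the ribosomal stalk protein gene, was at 0.52 in tgs1, and TUF1, the mitochondrial elongation factor, at -0.52. SPL2 was at -0.60 in ynr004w. There were 224 genes higher and 229 lower in tgs1, against 54 and 44 over single arrays, and 165 and 157 in ynr004w, against 32 and 29. Leaving out the 25 min point of tgs1 lowered its count to 286, and leaving out the 25 or 40 min point of ynr004w lowered its count to 170 or 148.

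Ribosomal protein genes shifted up at 16 °C with 53 higher and 15 lower in tgs1, or 54 and 15 adjusted over the list alone (adjusted p = 0.000163; adjusted p = 0.762 with an estimated correlation). In ynr004w 71 were higher and 5 lower, or 78 and 5 adjusted over the list alone, with RPL17A at 0.50 and RPS24A at 0.42 (adjusted p = 4.05e-14; adjusted p = 0.611 with an estimated correlation). Without the class A probes the call turned down in tgs1 (adjusted p = 0.378) and ended in ynr004w (adjusted p = 0.535), and medians over probes gave 0.697, turned down, and 0.351. Of 80 intron-containing other genes 32 fell and 10 rose in tgs1, or 34 and 10 adjusted over the list alone, ERV41 at -0.49 and ERD2 at -0.42 (adjusted p = 0.0295; adjusted p = 0.762 with an estimated correlation), a call lost with medians over probes (0.109). Ribosome biogenesis genes shifted up in ynr004w with 9 of 29 higher, the same adjusted over the list alone, SPB1 at 0.20 and NOP2 at 0.17 (adjusted p = 0.012; adjusted p = 0.708 with an estimated correlation), a call lost over single arrays (0.0999). Respiration genes shifted down in ynr004w with 2 of 4 lower, the same adjusted over the list alone, RIP1 at -0.27 and QCR9 at -0.18 (adjusted p = 0.0499; adjusted p = 0.611 with an estimated correlation). That call was lost with the ratios as deposited (0.0515), over single arrays (0.0964), with medians over probes (0.0511) and with centring on genes of 1 probe (0.0516).

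The change from 30 °C to 16 °C was tested within each strain, and no gene passed in either (limma; 180 genes in tgs1 and 118 in ynr004w at unadjusted p under 0.05; 0 in each over single arrays, with 15 and 9 unadjusted). The highest and lowest genes in tgs1 whose arrays did not overlap between the temperatures were RPP0 at 0.51 ± 0.12 (adjusted p = 0.11) and BRR1, a spliceosomal snRNP gene, at -0.32 ± 0.09 (adjusted p = 0.133). In ynr004w they were MFA2 at 0.56 ± 0.12 (adjusted p = 0.223) and POP6 at -0.25 ± 0.09 (adjusted p = 0.345). Leaving out the 40 min point of tgs1 gave 26 genes in tgs1. In the direct comparison of tgs1 with ynr004w at 16 °C, 5 genes were higher in tgs1 and none lower with the time points taken as replicates. Arrays scaled to one spread gave 13 higher and 3 lower, centring on genes with 1 probe 8 and 2, and a term for the time point, added after the data were seen, 9 and 4, among them all 5. With that term KAR2 was at -0.30 ± 0.04 (adjusted p = 0.0305) and TGS1 itself at -0.27 ± 0.05 (adjusted p = 0.0396), while MATALPHA1 at 0.32, GTS1 at 0.51 and STE3 at 0.43 did not pass (adjusted p = 0.0525, 0.0544 and 0.0987). COS8 (0.43 ± 0.06, adjusted p = 0.0171) was higher on every tgs1 array than on any ynr004w array. The other 4, whose arrays overlapped between the strains and which were named after their values were seen, were SPL2 (0.50 ± 0.06, adjusted p = 0.00616), ASP3-1 (0.30, adjusted p = 0.0368) and the mitochondrial tRNA genes tY(GUA)Q (0.43) and tW(UCA)Q (0.35). None passed over single arrays, where adjusted p lay between 0.379 and 0.998; 143 genes passed unadjusted, or 26 over single arrays, and leaving out the 10, 25 or 40 min point gave 3, 0 or 50 genes for tgs1 and 1, 0 or 10 for ynr004w.

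The mating type genes separated the strains most. MF(ALPHA)1 was between 4.78 and 5.57 on the 4 arrays of YPR045C and ist3 and between -5.44 and -3.75 on the 16 arrays of tgs1 and ynr004w. In csn12, MF(ALPHA)1 was at 0.06, MFA1 at -1.13 and MATALPHA1 at 1.06. It was at 0.60 in csn9, 0.61 in pci8 and 0.34 in isy1, while STE3 was at -0.04, -0.20 and 0.25. Between ist3 and tgs1 at 30 °C MF(ALPHA)1 differed by 9.77 ± 0.28 (adjusted p = 3.96e-09), and between YPR045C and csn12 by 4.78 ± 0.28 (adjusted p = 2.37e-06).

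**Figure D2:**
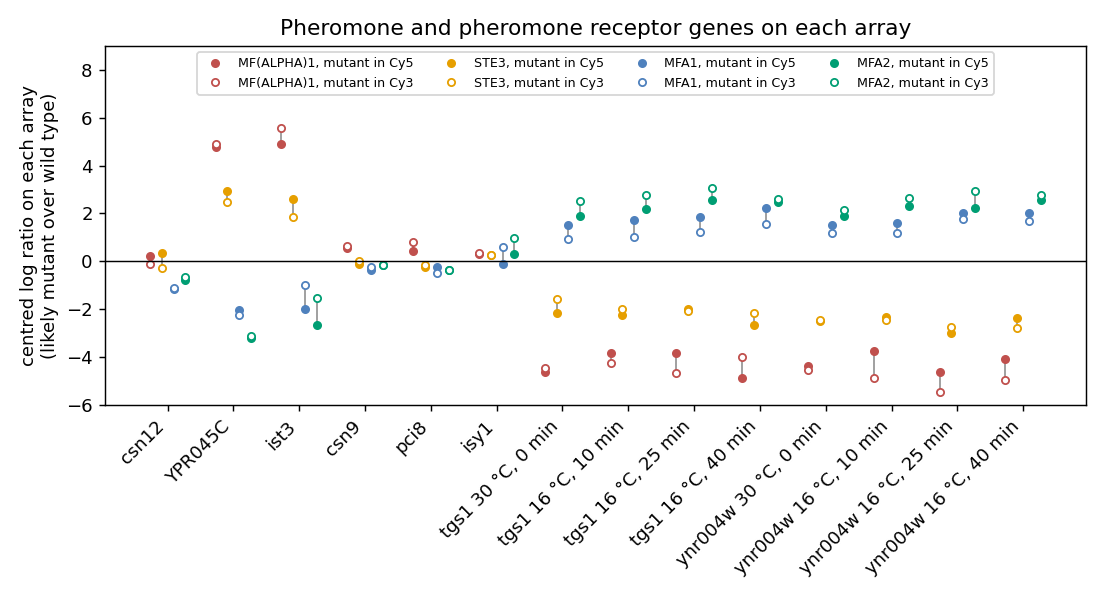
Centred log ratio, likely mutant over wild type, of the alpha genes MF(ALPHA)1 and STE3 and the a genes MFA1 and MFA2 on each array, filled for the mutant in Cy5 and open for the mutant in Cy3, joined within a pair. In YPR045C and ist3 the alpha genes are above 0 and the a genes below, and in all 8 pairs of tgs1 and ynr004w the reverse.

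The array was built to follow splicing, and 188 genes with 3 probes had 2 of them in linked wells of the print layout. No source used here gives the class of a probe, so intron retention was not measured. As a substitute chosen after the data were seen, the linked probes were called class A and class B by a rule on layout position read from ist3, and the remaining probe class C. In ist3 that rule placed A above B in 116 of 118 genes whose linked probes were over 0.4 apart, by the rule's own making, the exceptions being RPO26 and YRA1. The same rule, not fitted to the other strains, placed A above B in 53 of 53 such genes in tgs1 and 49 of 49 in ynr004w at 30 °C, 73 of 83 in isy1, 24 of 25 in YPR045C, 23 of 33 in csn12, 9 of 29 in csn9 and 8 of 35 in pci8.

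Class A was compared with the mean of B and C in 187 genes. In isy1 it was higher in 98 and lower in 12 (58 and 2 over single arrays), with RPS17B at 2.15 ± 0.15 and RPL36A at 2.08 but QCR10 at -0.59 and ACT1 at -0.56. At 16 °C it was higher in 143 and lower in 2 in tgs1 (115 and 0), and in 140 and 3 in ynr004w (104 and 0); RPS18B was at 1.59 ± 0.07 and 1.40 ± 0.07. At 30 °C it was higher in 65 genes in tgs1 (22) and 60 in ynr004w (17) and lower in none, RPS21A at 1.37 and RPS22B at 1.14 leading. In csn12 it was higher in 34 and lower in 12 (7 and 0), DBP2, an RNA helicase, at 1.26 ± 0.12, and in YPR045C in 30 and 2 (1 and 0), RPS14B at 0.79. In csn9 class A was higher in 4 and lower in 15 (0 and 0), VPS29 at -0.74, and in pci8 in 8 and 26 (0 and 1), RPL37A at -0.92. In ist3, whose values set the classes and so their direction, it was higher in 139 and lower in 4 (99 and 1), which is given as a size only, RPL35A at 2.12 and STO1, the large cap-binding subunit, at 1.87. Class A was above 0 before any test in 153 genes in YPR045C and in tgs1 at 30 °C, and in 127 in csn12, but in 61 in csn9 and 65 in pci8. The counts past the test at 16 °C rest on 3 pairs per strain and those at 30 °C on 1, so they differ in power.

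The median contrast over 74 ribosomal protein genes was 0.71 in isy1, 0.69 in tgs1 and 0.68 in ynr004w at 16 °C, and 0.43 and 0.36 in tgs1 and ynr004w at 30 °C, against 0.18, 0.24, 0.20, 0.14 and 0.18 over the 113 other genes. It was 0.21 against 0.13 in YPR045C, 0.11 against 0.08 in csn12, -0.10 against -0.10 in csn9 and -0.10 against -0.09 in pci8, and 0.89 against 0.32 in ist3, whose values set the classes. These differences were not tested. Before any test, the contrast was higher at 16 °C than at 30 °C in 148 of 187 genes in tgs1 (median difference 0.14) and in 139 in ynr004w (0.11). Far fewer passed the test, which has 1 pair at 30 °C in each strain. From 30 °C to 16 °C the contrast rose in 2 genes in tgs1 and 3 in ynr004w and fell in none (limma; 43 and 35 at unadjusted p under 0.05; 0 in each over single arrays). No gene differed between tgs1 and ynr004w at 16 °C (limma; 7 unadjusted; 0 over single arrays). Leaving out the 10 min point of tgs1 gave 41 genes for the change with temperature in tgs1, 29 in ynr004w and 2 between the strains, and 64 in YPR045C, 57 in csn9 and 61 in pci8 against wild type.

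**Figure D3:**
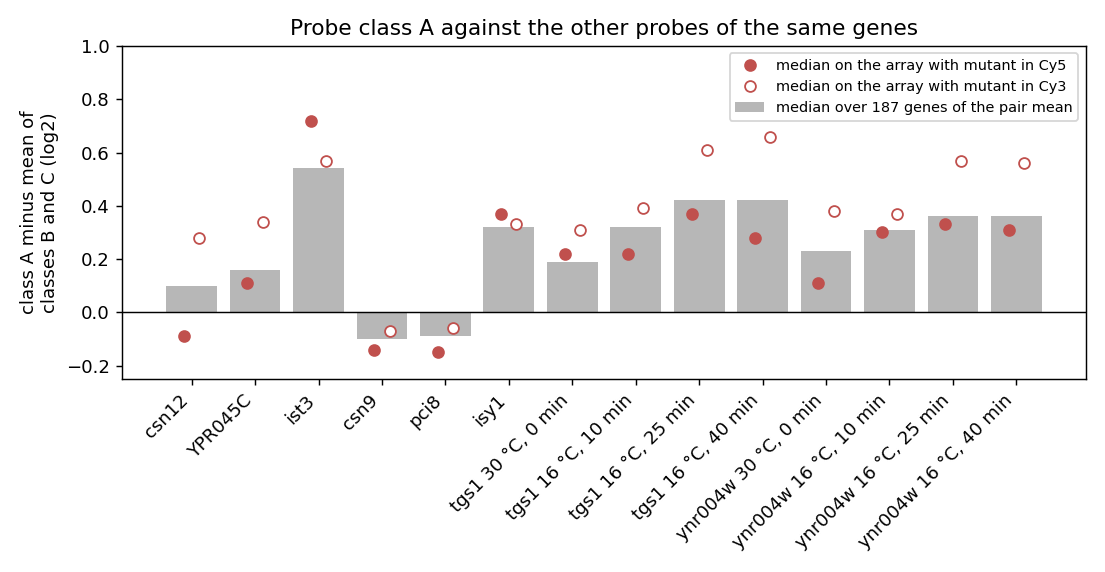
Median over 187 genes of class A minus the mean of classes B and C (log2) in each pair; bars show the pair mean and points the single arrays, filled for the mutant in Cy5 and open for Cy3. The bar is 0.54 in ist3, 0.32 in isy1, -0.10 in csn9 and -0.09 in pci8, and the csn12 arrays lie on both sides of 0 (-0.09 and 0.28).

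Across the 10 conditions, 29 of 140 tests of fixed lists passed with the preset correlation of camera and 0 with an estimated one, where the lowest adjusted p was 0.599. Core spliceosome genes (62) shifted in no strain, with 18 higher and 20 lower in ist3 and 12 and 15 in csn12, and the lowest list adjusted p was 0.219. Genes of the RES and Prp19 complexes (18) shifted in none either (lowest adjusted p = 0.127), with 2 higher and 7 lower in ist3. The stress list of 4 genes (lowest adjusted p = 0.0811) held HSP104 at 1.21 in csn12 and GPD1 at -0.82 in ist3. The copper list of 3 genes had a lowest adjusted p of 0.107, the list of 10 meiotic genes 0.0547 and the 3 measured deleted genes 0.505.

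By Pearson r across 982 genes, tgs1 and ynr004w at 30 °C ranked first of the 28 pairs of strains at r = 0.88 (Spearman 0.61), and r = 0.69 without the mating type and deleted genes. YPR045C and ist3 followed at r = 0.81, or 0.66 without those genes, but were the more alike by Spearman (0.70), and by Pearson over genes with 1 probe without those genes (0.68 against 0.66), and csn9 and pci8 at r = 0.65 (Spearman 0.61). The pair YPR045C and csn12 ranked 6 of 28 at r = 0.30 (Spearman 0.47), or 0.41 without those genes, and stood at 0.75 and 0.60 without replicate 1 and 2, where the dye effect does not cancel. YPR045C and ynr004w correlated at r = -0.54 (Spearman 0.38), and pci8 and isy1 at r = -0.34. Genes are not independent replicates. The 3 most alike pairs each share the start of the array codes, which may mark a batch, and in a simulation 2 unchanged strains that share a wild-type RNA correlated at r = 0.5 if all RNAs vary alike; whether RNA was shared is not stated, so strain, batch and control cannot be told apart.

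**Figure D4:**
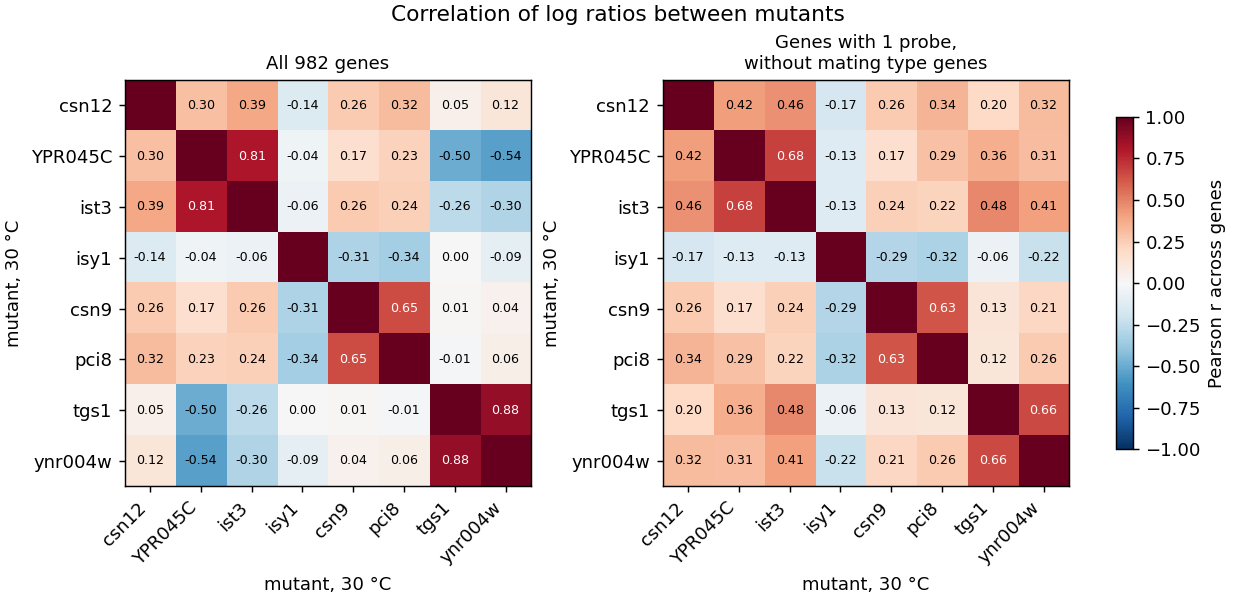
Pearson correlation across genes of the log ratios of each pair of mutants at 30 °C, for all 982 genes and for genes with 1 probe without mating type and deleted genes. The cell of tgs1 and ynr004w is 0.88 and then 0.66, and that of YPR045C and ynr004w turns from -0.54 to 0.31.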

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

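The tests of the mating type pattern were chosen after its values had been seen, as was the test of a shared wild-type RNA. The predictions of the other tests weighed here were written beforehand. Those on the probe classes, with the split by probe number, still came after the classes had been read from the data.

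The mating type genes differed in direction between strains. Between ist3 and tgs1 at 30 °C MF(ALPHA)1 differed by 9.77 ± 0.28 (adjusted p = 3.96e-09), MFA2 by -4.31 ± 0.14 (adjusted p = 1.08e-08) and STE3 by 4.09 ± 0.21 (adjusted p = 3.44e-07), each with one sign on both arrays of each pair. A single array turned the wrong way is argued against, since MF(ALPHA)1 had one sign on both arrays, by at least 1, in 10 of the 10 affected pairs. These pairs were picked by their values, and a pair with a turned array would average near 0. On the single arrays of csn12, csn9, pci8 and isy1, however, MF(ALPHA)1 lay only between -0.11 and 0.79. Both arrays of a pair turned together stays open: ist3 and tgs1 correlated at r = 0.48 over genes with 1 probe outside this group. A clearly negative value would have spoken for it, but a positive one excludes nothing, since the true likeness of the mutants is unknown. A candidate explanation is that mutant and wild type were of opposite mating type, as the alpha genes and a genes moved against each other on both arrays in 10 of 10 pairs, but mating types are not given in the sources used here and the data cannot tell this from an effect of the deletions.

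Probe class A stood above classes B and C more often than below among the genes past the test in isy1, tgs1, ynr004w, YPR045C (30 higher, 2 lower) and csn12 (34 and 12), and in ist3 by the way the classes were set, but below more often in csn9 (4 and 15) and pci8 (8 and 26). Unequal dye bias as the only cause is argued against, since the median contrast had one sign on both arrays in 13 of 14 pairs, the exception being csn12. Its size did differ between the dyes. The median was higher with the mutant in Cy3 in every pair except those of ist3 and isy1. In tgs1 after 40 min at 16 °C it was 0.66 against 0.28. That class A holds intron probes, so that the contrast would follow unspliced RNA, is a hypothesis. Introns of paralogous ribosomal protein genes differ, so the dye bias of intron probes should correlate less across paralog pairs. Over 25 pairs r was 0.21 in class A, 0.51 in B and 0.41 in C; the difference of -0.19 (bootstrap interval -0.6 to 0.34) leaves it open, and the contrast may also come from the position of the probes on the slide.

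The tgs1 and ynr004w strains were alike at 30 °C. Mating type genes alone are argued against (r = 0.69 without them), as are class A probes alone (r = 0.66 over genes with 1 probe without mating type genes). A wild-type RNA shared by both strains at each time point could add to it: the mean correlation was 0.11 higher at the same time point (0.7) than at different ones (0.59, from 0.35 to 0.73), and the true matching of time points was the highest of 24 ways, though the next highest was also 0.7 as rounded. Time itself would give the same, so this cannot be told apart. A shared effect of both deletions stays open and untested. So does a mating type mismatch shared by both strains, since other genes, such as those of the pheromone response, stayed in.

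Probes without a gene name, which no comparison used, also carried signal. In ist3 the furthest from 0 was at 3.07 (limma, adjusted p = 1.14e-09), in isy1 at -2.14 (adjusted p = 1.38e-08) and in tgs1 at 16 °C at 1.56 (adjusted p = 7.08e-09). The probe furthest in isy1 was also the furthest in tgs1 (-1.13) and ynr004w (-1.49) at 30 °C.

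For the 5 genes that differed between tgs1 and ynr004w at 16 °C, the 6 pairs make 10 splits into 3 and 3, too few for a share under 0.05; the real split gave 5 genes and the highest other 4. The splits do not keep time points matched.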

How the results depend on the processing

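Leaving out class A, centring on genes with 1 probe, class B or C as the reference, a term for the time point, and splits by probe number were chosen after the data were seen. Of 5324 values of named genes under the alternatives, 5070 kept direction and side of the threshold, 250 lost the threshold and 1 gained it. The losses were uneven: 107 were lost and 220 kept in the dye-term fit. Without replicate 2, 55 were lost and 272 kept, and without replicate 1, 25 and 302. These genes were picked for one sign on every array, so they could not turn when either array of the pairs was left out. The 3 that turned were RPL17B in tgs1 at 30 °C without class A (-0.06) and RPS0B in ynr004w at 16 °C with medians (-0.06) and without class A (-0.11). No count moved by over 1.5 times with the ratios as deposited or with probes measured on every array. The planned centring on intronless genes and the split by intron were not run, since no intron annotation was given, and intron retention was not measured. Few arrays limit the depth: signal over background is not given. The cause of a move was not tested, except that stricter thresholds leave less by construction. Leaving out a time point raised some counts and lowered others.
The dye-term fit, which is the replicate block, gave 46 genes in csn12, 10 in YPR045C, 76 in ist3, 3 in csn9, 10 in pci8, 95 in isy1, 9 in tgs1 and 9 in ynr004w at 30 °C, 98 and 61 at 16 °C, and 0 between those strains. For the class contrast it gave 7, 1, 0, 1 and 60 in csn12, YPR045C, csn9, pci8 and isy1, 22 and 17 in tgs1 and ynr004w at 30 °C, and 0 and 0 for 16 °C minus 30 °C. Array numbers mark dye orientation only. A call lost there did not pass when the error came from the arrays of the pairs. It therefore rests on the smaller spread taken from the 16 °C time points. At adjusted p under 0.01 counts were 187 (csn12), 75 (YPR045C), 92 (csn9), 140 (pci8), 241 (isy1), 15 (tgs1 30 °C), 12 (ynr004w 30 °C), 269 (tgs1 16 °C), 162 (ynr004w 16 °C) and 1 (tgs1 minus ynr004w). With at least 1 log2 unit they were 11, 6, 6, 1, 2 and 18 in csn12, YPR045C, ist3, csn9, pci8 and isy1, 6 and 7 in tgs1 and ynr004w at 30 °C, 7 and 7 at 16 °C, and 0 between strains. Scaled arrays gave 468 (csn9), 536 (pci8), 18 (tgs1 30 °C) and 16 (tgs1 minus ynr004w, 13 higher and 3 lower), and class contrasts of 82 (csn9), 91 (pci8) and 18 (ynr004w 16 °C minus 30 °C). With 8 strain groups counts were 414 and 294 in tgs1 and ynr004w at 30 °C and 2 between strains, and class contrasts 22, 3, 6 and 20 in csn12, YPR045C, csn9 and pci8 and 142 and 137 in tgs1 and ynr004w. Medians over probes gave 2 (tgs1 16 °C minus 30 °C) and 11 (tgs1 minus ynr004w), leaving out class A 11 and centring on genes with 1 probe 10 (8 higher, 2 lower). A term for the time point gave 13 between strains (9 higher, 4 lower) and a class contrast of 1. Centring on genes with 1 probe also moved the csn12 split to 141 higher and 219 lower. Robust eBayes gave 1 class contrast in tgs1 16 °C minus 30 °C. Class B alone gave 15 in YPR045C, 10 and 0 in tgs1 and ynr004w 16 °C minus 30 °C and 1 between strains; class C alone gave 31 in csn9 and 1 and 0.
Without replicate 1 or 2, or a time point, counts ran from 326 to 602 in csn12, 157 to 596 in YPR045C, 175 to 380 in pci8, 28 to 645 in tgs1 and 27 to 550 in ynr004w at 30 °C, 286 to 763 and 148 to 708 at 16 °C, 0 to 94 in tgs1 16 °C minus 30 °C and 0 to 55 between strains. Class contrasts ran from 34 to 113 in csn12, 13 to 111 in YPR045C, 4 to 57 in csn9, 16 to 61 in pci8, 60 to 101 and 51 to 107 in tgs1 and ynr004w at 30 °C, 1 to 41 and 0 to 29 for 16 °C minus 30 °C, and 0 to 2 between strains. With one array of each pair the dye effect does not cancel.
The estimated correlation left 0 of 29 list shifts. Still past the threshold in the same direction were 28 as deposited, 29 scaled, 26 with the dye term, 21 with medians and 23 without class A. The direction turned for 4 with medians and for 4 without class A, and for none in the other settings. Similarity without replicate 1 or 2 was 0.60 to 0.75 for csn12 with YPR045C, 0.83 to 0.87 for YPR045C with ist3, 0.56 to 0.61 for csn9 with pci8 and 0.91 to 0.93 for tgs1 with ynr004w. Without mating type genes it was 0.66 for YPR045C with ist3 and 0.69 for tgs1 with ynr004w, and over genes with 3 or 4 probes 0.63, 0.73 for csn9 with pci8 and 0.80.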

Other observations

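The lists in this part were drawn from the array after the data were seen. The list of 64 tRNA genes shifted with the preset correlation in all but 1 of 10 conditions, with members going both ways in several. It shifted down in pci8 with 33 lower and 3 higher (adjusted p = 7.56e-10; adjusted p = 0.433 with an estimated correlation), led by YNCB0018W at -1.51, and in csn12 with 23 lower and 2 higher (adjusted p = 4.02e-05; adjusted p = 0.433 with an estimated correlation). Downward shifts also passed in csn9 (5 higher, 20 lower, adjusted p = 0.00117), YPR045C (0 and 10, 0.00275), ist3 (9 and 28, 0.0211) and tgs1 (0 and 2, 0.0214) and ynr004w (0 and 6, 7.8e-08) at 30 °C. It shifted up in isy1 with 32 higher and 12 lower (adjusted p = 0.000577), YNCD0021C at 2.03, and in tgs1 at 16 °C with 37 higher and 13 lower (adjusted p = 0.000354). In ynr004w at 16 °C adjusted p was 0.859. None of these held with an estimated correlation, and of 30 tests of such lists 24 passed with the preset correlation and 0 with an estimated one. Over single arrays 0 tRNA genes passed higher and 7 lower in csn12, 0 and 0 in YPR045C, and 0 and 3 in ist3. The counts there were 0 and 2 in csn9, 0 and 4 in pci8 and 16 and 1 in isy1.

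TDH1 ran in opposite directions between strains. It was at 2.33 in isy1 and at -1.35 in tgs1 and -1.72 in ynr004w at 30 °C, and at -0.84 in csn12, with one sign on both arrays of each; these differences between strains were not tested. HTA1 was at -1.19 in isy1 and 0.60 in pci8. SPL2, of the phosphate pathway, was at -0.75 in ist3 and -0.60 in ynr004w at 16 °C.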
